A study of Zea mays with 2 samples.

How the data were processed

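Messenger RNA of maize (Zea mays) endosperm, the starch and protein storing tissue of the kernel, was profiled by RNA sequencing at 19 days after pollination in a wild type and in the fl4 (floury4) mutant. The labels give 2 samples, 1 per genotype, each with 1 file. The series design speaks of triplicates. The files hold a single value per feature and genotype, and whether the replicates were pooled or averaged is not given in the sources used here.

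The deposited values are FPKM, a read density scaled by feature length and by the number of mapped fragments, per the file headers, as computed by the authors. Bowtie 0.12.2 is named in the submitters' processing notes. The quantification program, the genome build, the annotation and any filter are not given in the sources used here. Both files list the same 65535 features in the same order, so that each file with its header has 65536 lines, which is the row limit of older spreadsheet programs. No feature is at 0 in both libraries. Whether further features were cut off at that limit is not known.

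Each feature is identified by a chromosome and a span, with no gene name or identifier. The positions of 8 features read as decimal numbers. These 8 carry 0.0067% of the total FPKM in fl4 and 0.0062% in the wild type, and were left out of all comparisons. The other 65527 features fall on 58456 distinct spans, of which 10 overlap another. Of the spans, 6286 are listed for more than 1 feature, with up to 8 features on a span. A span shared by several features therefore behaves as a merged locus, and 1 position may stand for several genes or transcripts. None of the identifiers (0 of 65535) matched the RefSeq gene table used for names, which belongs to another named assembly, so positions were not converted and no gene name was assigned. The 22 gene lists fixed before the data were examined (zeins, endoplasmic reticulum chaperones, starch synthesis, markers of aleurone, transfer layer and embryo, and others) could not be filled and are not analysed here, nor is the share of zeins. Positions are given as in the files, and windows are counted from the start of each chromosome.

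For each feature the log2 ratio of fl4 to wild type was computed as log2((FPKM + 1)/(FPKM + 1)), with the pseudocount of 1 FPKM understating changes of low features. Features with at least 1 FPKM in either library were kept, and a 2-fold difference in either direction was counted. This is a rule of size and not a test. With 1 library per genotype there is no estimate of error between plants, no p-value is given, and every difference describes these 2 libraries. The rule for named features, fixed before the data were examined, took the largest differences among features with at least 10 FPKM and, for identifiers without names, allowed 2 higher and 2 lower features. All regions were chosen after the data were seen.

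FPKM was summed over windows of 1 Mb, and windows that reached 10000 FPKM in either library are described singly. An exact 0 in a table without counts can be a failed estimate, so the window sums use features above 0 in both libraries, and features listed at 0 are given separately. The share of 2-fold differences was scanned in 5 Mb windows with at least 20 features. Each window was compared with 10000 random sets of as many features drawn with the same numbers from 20 bins of mean expression. The percentile among these sets is a description, because genes are not replicates. Intervals on shares of features are 95% binomial intervals (Wilson, or exact where stated) and treat features as independent.

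Library depth is unknown. Among the 1000 features with the lowest FPKM times span, no log2 ratio (to 3 decimals) occurred in more than 4 features, so no step of single reads was visible and read counts were not recovered. The scan and the 2-fold rule were tested on simulated data built on 38591 features of this comparison, with the real log2 ratios shuffled within expression bins as noise and 200 features changed by a known fold. Features changed 2-fold were called in 52.5% of cases. With 100 of the 200 placed in 2 windows, 94.5% of features changed 4-fold and 99.0% of those changed 8-fold were called, and so were 10.6% of the unchanged features, because the shuffled ratios keep the spread of the data. Both of these windows were found at each fold, with at most 1 other window among 416. With 60 placed over 4 windows, at most 1 of the 4 was found, so the scan misses weak local excesses. Shuffling removes any clustering of neighbours, which the simulation therefore does not cover.

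Alternatives covered the pseudocount (0.1 and 5 FPKM), the filter (none and 5 FPKM), the fold threshold (1.5 and 4), and the scaling. The scaling alternatives were median centring, a trimmed mean factor in the style of TMM, and equal totals without the 20 most abundant features. Features listed at 0, spans under 300 bp, sums per span and 1 feature per 200 kb were added after the data were seen. Computation used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with Matplotlib 3.10.9.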

Results

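Endosperm RNA of the fl4 mutant was compared with that of the wild type at 19 days after pollination, when the endosperm fills with starch and with zeins, the alcohol-soluble storage proteins of maize. The floury4 mutation gives soft, opaque kernels and has been reported to lie in an alpha-zein gene. The comparison addresses which transcripts differ in abundance in the mutant endosperm. Each genotype is represented by 1 library and values are therefore given without an error. The summed FPKM was 1132704 in fl4 and 1025980 in the wild type, 1.104 times as much in the mutant, and the median feature stood at 1.45 and 1.40 FPKM. At least 1 FPKM was reached by 36055 features in fl4, by 35726 in the wild type and by 33190 in both. Features carry positions and no gene names, so the gene altered in fl4 and the zein genes were not singled out. Sequencing depth is unknown, and the precision of low values is unknown with it.

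Most transcripts were present at similar levels in mutant and wild type endosperm. Of 38591 features with at least 1 FPKM, 34495 (89.4%) lay within 2-fold, 2328 (6.03%) were at least 2-fold higher in fl4 and 1768 (4.58%) at least 2-fold lower. Of the higher features 646 were listed at 0 in the wild type, and of the lower features 387 were listed at 0 in fl4. Short features contributed heavily. Among 2159 features with a span under 150 bp 52.8% differed 2-fold, against 6.75% of the 34324 features with a span of at least 300 bp.

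**Figure D1:**
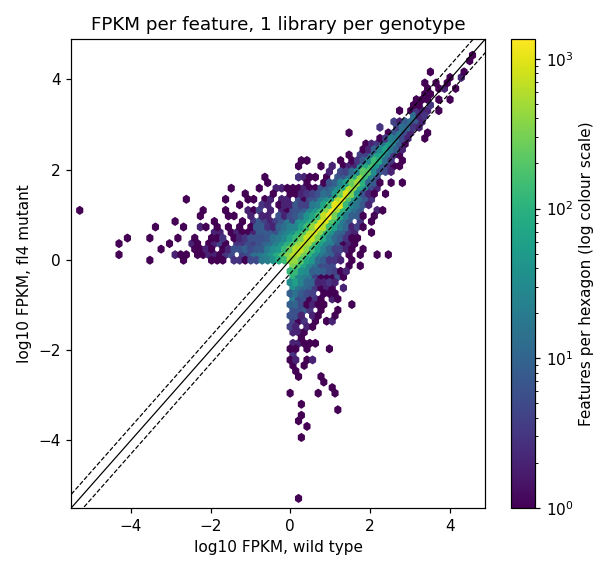
FPKM of each feature in the wild type (x axis, log10 FPKM) and in fl4 (y axis, log10 FPKM), for features above 0 in both libraries and at least 1 FPKM in either; colour gives the number of features per hexagon, the solid line equality and the dashed lines a 2-fold difference. Most features lie between the dashed lines.

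The middle of the log2 ratios was tighter at high expression, with a robust SD of 0.70 in the lowest of 10 expression bins and 0.26 in the highest, but the plain SD was 0.80 and 0.69, with a highest value of 1.05 in the fourth bin. The lowest bin is partly shaped by the filter, which asks for 1 FPKM in either library before binning on the mean of both. A low mean then goes with unequal values. How the share of 2-fold differences varied with abundance depended on the grouping. It was 21.7% in the lowest of these bins and 5.23% in the highest, but among features above 0 in both libraries and grouped by the higher of the 2 values it was 7.80% at 1 to 10 FPKM, 8.56% at 10 to 100, 9.20% at 100 to 1000 and 14.1% (14 of 99 features) at 1000 FPKM or more. The median log2 ratio was 0.01 in the lowest bin and 0.16 in the highest, as the values were scaled by the authors. The middle of the distribution over features with at least 1 FPKM in both libraries was 0.07. With totals made equal after leaving out the 20 most abundant features, ratios shift down by 0.15, and the counts become 1910 higher and 2017 lower, so that the excess of higher over lower features depends on the scaling.

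Among the most abundant transcripts the balance between the genotypes rested on features listed at 0 in the wild type. Features reaching 1000 FPKM numbered 107 and made up 34.1% of the total FPKM in fl4 and 33.3% in the wild type. Of the 99 above 0 in both libraries, 54 were higher and 45 lower in fl4, and their summed FPKM was 315571 in fl4 and 341530 in the wild type, a log2 ratio of -0.11. With the other 8 features, all listed at 0 in the wild type, the fl4 sum was 386036 FPKM and the log2 ratio 0.18. The sum over features of 100 to 1000 FPKM above 0 in both libraries had a log2 ratio of 0.14, and of -0.012 with equal totals. Of the 99 features, 9 were at least 2-fold higher and 5 at least 2-fold lower. Of the 5 lower features 4 lay in the window from 5 to 6 Mb of chromosome 4 and 1 in the window from 18 to 19 Mb of chromosome 7. The 9 higher features lay in 9 different windows, on chromosomes 2, 4, 6, 8 and 9, 1 of them the window from 5 to 6 Mb of chromosome 4. These counts leave out the 8 features listed at 0 in the wild type. Those 8 lay in the same windows of chromosomes 4 and 7 and in that from 120 to 121 Mb of chromosome 7. With the 8 counted, higher features also gathered in these windows, so clustering there was not confined to the lower features. Whether the degree of clustering differed was not tested. The 10 highest features of each library had 6 in common. Of the 10 highest in the wild type 5 lay on chromosome 7 and 3 on chromosome 4, and of the 10 highest in fl4 4 lay on chromosome 7 and 3 on chromosome 4.

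Transcript abundance was concentrated in a few short regions. The 9 windows of 1 Mb that reached 10000 FPKM in either library held 23.7% of the total FPKM in fl4 and 22.8% in the wild type. Over features above 0 in both libraries, 6 of the 9 windows were lower in fl4 and 3 were higher. Over all features, with those listed at 0 in the wild type, 3 were lower and 6 higher. The other scalings tried turned none of the 9 directions over features above 0 in both libraries. Which genes these windows hold is not given by the files, and whether near-identical copies exchanged reads was not tested.

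Of the 6 windows that were lower over features above 0 in both libraries, 3 were also lower over all features. The window from 21 to 22 Mb of chromosome 4 summed to 12259 FPKM in fl4 and 22168 in the wild type, 1.81-fold lower, with 94.3% of the fl4 sum in a single feature. The window from 183 to 184 Mb of chromosome 2 stood at 27338 against 35007 FPKM. The window from 44 to 45 Mb of chromosome 6, in which 1 feature gave 99.5% of the sum in either library, stood at 34561 and 37673 FPKM, a log2 ratio of -0.12. In the other 3 the direction turned with the features listed at 0. The window from 5 to 6 Mb of chromosome 4 summed to 17847 and 30248 FPKM over features above 0 in both, and to 40120 and 30253 over all features. Of its 12 features with at least 100 FPKM and above 0 in both libraries, 7 were at least 2-fold lower and 2 at least 2-fold higher. A further 8 features of at least 300 FPKM in fl4 were listed at 0 in the wild type. The window from 18 to 19 Mb of chromosome 7, the richest of the wild type, summed to 46366 and 69534 FPKM over features above 0 in both, and to 87136 and 69534 over all features. There 10 of 12 features with at least 100 FPKM and above 0 in both libraries were lower, 4 of them by 2-fold or more. A further 1 feature of at least 300 FPKM in fl4 was listed at 0 in the wild type. The window from 120 to 121 Mb of chromosome 7 stood at 5967 against 7741 FPKM, and at 14958 against 7741 over all features.

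Higher sums in fl4 with and without the features listed at 0 were found in 3 windows. The window from 121 to 122 Mb of chromosome 6 summed to 14089 FPKM in fl4 and 3762 in the wild type, 3.74-fold higher, and a single feature gave 96.3% of the fl4 sum. The window from 29 to 30 Mb of chromosome 4 summed to 23332 and 16446 FPKM, 1.42-fold higher in fl4. The window from 161 to 162 Mb of chromosome 1 summed to 14286 and 11810 FPKM, 1.21-fold higher.

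**Figure D2:**
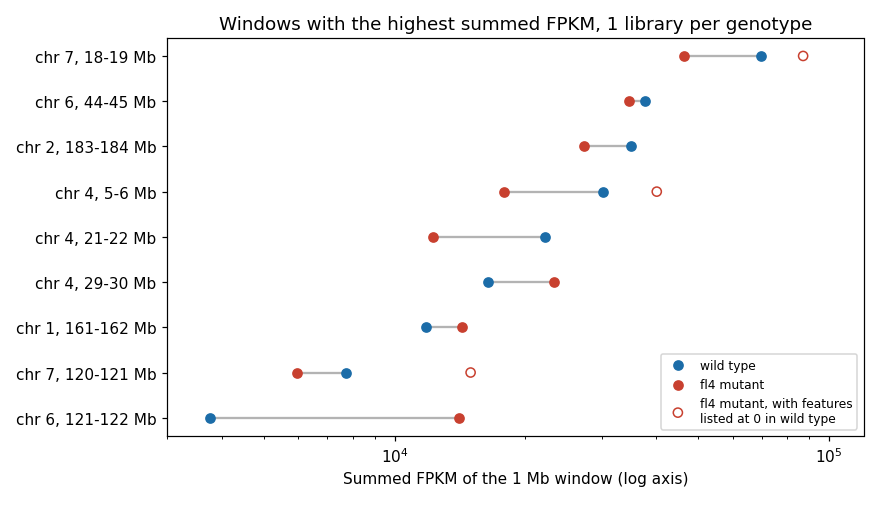
Summed FPKM (x axis, log scale) of the 9 windows of 1 Mb that reached 10000 FPKM, 1 row per window; filled points are sums over features above 0 in both libraries in the wild type (blue) and fl4 (red), and open points add features listed at 0 in the wild type. The filled red point lies left of the blue point in 6 windows, and in 3 windows the open point lies to the right of both.

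In 3 of these windows the direction depended on loci listed at 0 in the wild type. There were 6 loci with a feature above 1000 FPKM in fl4 and exactly 0 in the wild type, 4 on chromosome 4 and 2 on chromosome 7. They held 11 features and 71997 FPKM in fl4, 6.36% of its total. With these features added, the log2 ratio turned from -0.58 to 0.33 in the chromosome 7 window from 18 Mb, from -0.76 to 0.41 in the chromosome 4 window from 5 Mb, and from -0.38 to 0.95 in the chromosome 7 window from 120 Mb. The deposited tables do not tell a failed estimate from absent transcript, so the balance of these 3 windows is open.

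The features selected by the rule for named features were likewise listed at 0 in one library. The feature at 18866466 to 18867189 of chromosome 7, with a span of 724 bp, stood at 40770 FPKM in fl4, the highest value of either library, and was listed at 0 in the wild type. A feature on the span from 120200893 to 120203011 of chromosome 7 stood at 8240 FPKM in fl4 and was listed at 0 in the wild type. In the other direction, the feature at 62004270 to 62004357 of chromosome 1, with a span of 88 bp, stood at 156 FPKM in the wild type and was listed at 0 in fl4. A feature on the span from 88263850 to 88264544 of chromosome 3 stood at 121 FPKM in the wild type and was listed at 0 in fl4. No fold change is given for them.

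Moderately abundant regions mostly differed little. Of the 176 windows of 1 Mb with at least 1000 FPKM, 127 were higher and 49 lower in fl4, with a median log2 ratio of 0.17, close to the shift of 0.15 that equal totals bring. At least 2-fold differences were seen in 5 of them, 4 higher and 1 lower. One further window lay just short, at an absolute log2 ratio of 0.9998, and with equal totals without the 20 most abundant features the counts were 3 higher and 2 lower. Besides the window of chromosome 6 already described, the window from 118 to 119 Mb of chromosome 7 was 3.27-fold higher in fl4 (1076 against 330 FPKM). The window from 14 to 15 Mb of chromosome 2 was 2.56-fold higher (2444 against 954 FPKM), and that from 144 to 145 Mb of chromosome 9 was 2.13-fold higher (4224 against 1983 FPKM, a log2 ratio of 1.09). In these 3 windows 1 feature gave 80.5% to 93.3% of the fl4 sum. The window from 6 to 7 Mb of chromosome 7 was 2.39-fold lower (584 against 1394 FPKM).

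Features of the organelle genomes had low summed FPKM in both libraries. Messenger RNA was profiled and any filter is unknown, so these sums do not give organelle transcript abundance in the tissue. The 98 mitochondrial features summed to 51.1 FPKM in fl4 and 42.4 in the wild type, and the 43 chloroplast features to 6.96 and 5.77 FPKM. Of 15 mitochondrial features with at least 1 FPKM, 1 differed 2-fold. Their median log2 ratio of 0.11 stood at percentile 78.1 among 10000 random lists of the same size and expression. Only 2 chloroplast features reached 1 FPKM.

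Large differences were unevenly spread along the chromosomes. The share of features with a 2-fold difference was 10.6% over the genome and ranged over the numbered chromosomes from 8.87% on chromosome 5 to 12.9% on chromosome 4. Among 416 windows of 5 Mb, 2 exceeded each of their 10000 random sets, and they were adjacent, covering the first 10 Mb of chromosome 4. From 0 to 5 Mb 37 of 142 features differed 2-fold, and from 5 to 10 Mb 46 of 113. Together 83 of 255 features (32.5%, Wilson 95% interval 27.1% to 38.5%) differed, 46 higher and 37 lower in fl4, against 10.5% of features elsewhere. The window from 5 to 6 Mb alone held 30 differing features among 53, and without it 53 of 202 (26.2%) remained.

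In all 7 windows reached the 99.9th percentile of their random sets. Features drawn independently would give 0.416 such windows, but 2-fold differences of neighbouring loci went together across the genome, so more are expected without any special stretch. Of the other 5, 1 lay from 15 to 20 Mb of chromosome 4 (20 of 78 features), and 4 lay between 55 and 100 Mb of chromosome 3. Over that whole stretch of chromosome 3, 95 of 376 features (25.3%, Wilson 95% interval 21.1% to 29.9%) differed 2-fold, 40 higher and 55 lower in fl4. Its 5 Mb windows were uneven, with 13 of 30 features from 80 to 85 Mb and 1 of 30 from 75 to 80 Mb. These intervals cover counting of features only.

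**Figure D3:**
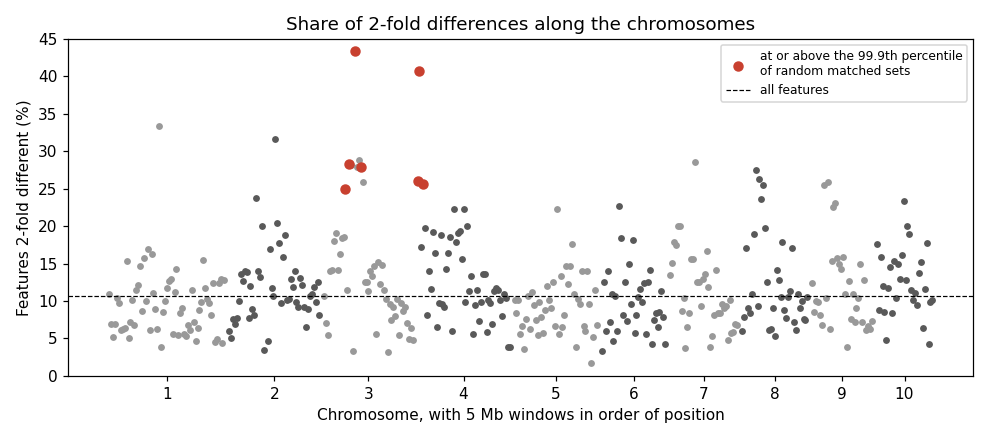
Share of features with a 2-fold difference (y axis, percent) in 5 Mb windows along chromosomes 1 to 10 (x axis); each point is a window with at least 20 features of at least 1 FPKM, red points reach the 99.9th percentile of random sets matched on expression, and the dashed line is the share over all features. The 7 red points lie on chromosomes 3 and 4, the highest at 43.3% and 40.7%.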

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

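Signal was present in data outside the comparisons, in the 8 features whose positions were not readable. They summed to 76.0 FPKM in fl4 and 63.3 FPKM in the wild type, and 6 of the 8 were higher in fl4. The difference was not tested, since each genotype has 1 library. The total FPKM of fl4 was 1.104 times that of the wild type, so part of the gap goes with the totals.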

How the results depend on the processing

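The settings for features at 0, span, sums per span, equal totals, 1 feature per 200 kb, and all settings for windows and segments were chosen after the data were seen. Of 119 alternative values, 87 stayed within the limits set for the result, 27 moved beyond them and 5 reversed. The number of features at least 2-fold higher and lower in fl4 (2328 and 1768) became 935 and 653 with a pseudocount of 5 FPKM, 1488 and 1069 with a minimum of 5 FPKM, and 1296 and 1021 with spans of at least 300 bp. It became 4589 and 3733 at a 1.5-fold threshold, 792 and 478 at a 4-fold threshold, and 3364 and 2745 with a pseudocount of 0.1 FPKM. The higher minimum left 23100 of 38591 features tested, and the span limit 34324. With the span limit the share of 2-fold differences itself fell from 10.6% to 6.75%, as it removed the short features, which differed most often. The causes of these drops were not otherwise tested. Higher features outnumbered lower ones in these settings, but with equal totals without the 20 most abundant features lower ones did, with 1910 higher and 2017 lower. That scaling also turned the log2 ratio of the summed features of 100 to 1000 FPKM from 0.14 to -0.012, and changed the counts of 1 Mb windows of at least 1000 FPKM that were 2-fold higher and lower from 4 and 1 to 3 and 2. The other 4 reversals were the sum over features of at least 1000 FPKM and the windows of chromosome 7 from 18 Mb, chromosome 4 from 5 Mb and chromosome 7 from 120 Mb, which went to 0.18, 0.33, 0.41 and 0.95 (log2) when features listed at 0 in the wild type were included. By construction those features cause the reversal. The share of 2-fold differences in the first 10 Mb of chromosome 4 (32.5%) moved to 26.2% with 1 feature per 200 kb, 24.2% without features at 0, 26.2% without the window from 5 to 6 Mb, 18.04% with a pseudocount of 5 FPKM, 18.6% without a filter, 48.6% at 1.5-fold and 13.7% at 4-fold. It lay above the highest random set in 13 of 14 settings, the exception being 1 feature per 200 kb. The share from 55 to 100 Mb of chromosome 3 (25.3%) moved to 19.2% with 1 feature per 200 kb, 19.5% without features at 0, 18.2% with at least 10 FPKM and 300 bp, 31.9% and 10.1% with pseudocounts of 0.1 and 5 FPKM, 13.03% without a filter, 38.8% at 1.5-fold and 11.2% at 4-fold. It lay above the highest random set in 11 of 13 settings, the exceptions being 1 feature per 200 kb and the limit of 10 FPKM and 300 bp. The alternatives chosen before the data were examined for gene list medians and for the zein share, and the scaling without zeins, were not run because no feature could be assigned to a list. Those for the named features were not run because all 4 are listed at 0 in 1 library and have no fold. No replicate could be left out, and no paired analysis was possible because each genotype has 1 library. Depth is unknown, so no limit from depth can be stated for any value.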

Other observations

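Features that share a span went in the same direction more often than shuffled partners. Among 963 spans with exactly 2 features of at least 10 FPKM, 70.7% had both features on the same side of equality, against 57.0% after shuffling the partners. The shuffle was made once and was not matched on expression, so its spread is not known. The median absolute difference of their log2 ratios was 0.21, against 0.34 after shuffling. Differences were also clustered beyond the stretches of chromosomes 3 and 4. Outside these, 615 pairs of neighbouring loci both held a 2-fold difference, where 100 shuffles within expression bins gave 443 on average and 490 at most. With the stretches of chromosomes 3 and 4 counted in, 14.2% of the features differed 2-fold in windows of 5 Mb with fewer than 60 features. In windows with at least 120 features 9.18% did.

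In the rest of this part, the tests of loci listed at 0, of the direction of the differences and of windows with few features were chosen after the values they rest on, or a plot of them, had been seen. The tests with 1 feature per 200 kb, without features at 0, and with at least 10 FPKM and 300 bp had their predictions written before their results were seen, though after the stretches themselves had been picked.

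The first pattern is the set of 6 loci above 1000 FPKM in fl4 and at exactly 0 in the wild type. Chance sampling of a low transcript is argued against by the share at 0 in the wild type, among spans of at least 300 bp. It was 9.64% of features of at least 1000 FPKM in fl4 (exact 95% interval 4.25% to 18.1%). At 100 to 1000 FPKM it was 0.30% (upper bound 0.875%), and at 300 to 1000 FPKM alone 1.47% (0.30% to 4.24%). The 8 features behind the 9.64% lay on 6 loci, so its interval, which treats features as independent, is too narrow. No feature of at least 1000 FPKM in the wild type was at 0 in fl4 (0 of 73). Its upper bound of 4.93% overlaps the interval for fl4. A failed estimate of the whole locus may be the cause, and in 5 of 5 loci with more than 1 feature every feature was at 0, but a locus absent or silent in the wild type line predicts the same. These remain unresolved because the tables carry no status for each estimate. A test on the reads of these loci would separate them.

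The second pattern is the excess of 2-fold differences in the first 10 Mb of chromosome 4. Zero estimates are argued against as its whole cause, since 24.2% of features above 0 in both libraries still differed (highest random set 14.98%). Low or short features are also argued against with 35.3% among features of at least 10 FPKM and 300 bp (highest random set 20.6%). Few features per window are argued against as the cause, because the 2 windows held 142 and 113 features, above the class of fewer than 60. Random sets of 2 windows with like feature numbers on other chromosomes reached at most 17.4%, against 32.5% in the stretch. The stretch was picked from the same scan, which biases its share upward. The higher of the 2 windows stood at 40.7% (Wilson 95% interval 32.1% to 49.9%). The highest of 64 windows with like feature numbers on other chromosomes stood at 17.9%, so such windows did not share the excess. Reads shared between neighbouring copies stay open, because 26.2% with 1 feature per 200 kb lay above the 95th percentile of random sets (16.7%) and below the highest (28.6%), on 42 features. A hypothesis is a segment that differs in sequence between the mutant and wild type lines, for example donor chromosome kept around a selected mutation; 44.6% of the differences went in the rarer direction, which such a segment allows and which does not single it out.

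The third pattern is the excess between 55 and 100 Mb of chromosome 3, a stretch picked from the same scan, which biases its share upward. Zero estimates are argued against as the whole cause (19.5% without features at 0, highest random set 14.9%). A general excess in windows with few features is argued against as the whole cause by the share of the stretch, 25.3%. Random sets of 9 windows, drawn from 139 like windows on other chromosomes, had a 95th percentile of 15.7% and a highest value of 22.1%. The upward bias of the share, and its Wilson lower limit of 21.1%, weaken this. The highest window alone does not decide it. At 43.3% (Wilson 95% interval 27.4% to 60.8%), that window is not beyond counting error of the highest of the 139, at 31.6%. Reads shared between neighbours stay open with 19.2% (highest random set 22.4%). Short features alone are argued against as the whole cause by a limit chosen after the data were seen. With spans of at least 300 bp 21.2% still differed (highest random set 13.6%). Low features stay open, because the limits on FPKM differed in outcome. At 5 FPKM or more 26.5% differed, above the highest random set (23.3%). With at least 10 FPKM and 300 bp it was 18.2%, on 121 features. That lay above the 95th percentile of random sets (14.9%) and below the highest (19.8%). A segment that differs between the lines may also apply here, with 42.1% of the differences in the rarer direction, and genotype itself was not tested apart from line background in either stretch.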
